A study of Homo sapiens with 4 samples.

How the data were processed

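Total RNA from NCI-H292 cells was labelled with biotin and hybridised to 4 Affymetrix gene arrays, 2 from cells given ginsenoside Rg5 with phorbol myristate acetate (PMA) and 2 from cells given vehicle with PMA, per the labels. The labels' protocols state a column-based extraction kit, fragmentation of the cDNA and end labelling, PMA at 10 ng/ml and a time of 24 h. The authors deposited 1 table of log2 intensities with a value for each of 18675 probes on each array. How those values were summarised and normalised, and with which software or genome build, is not given in the sources used here, so no genome coordinates are reported. The base of the logarithm is not stated either, and base 2 was taken from the range, since values reached 13.4 and the natural logarithm of a 16-bit scanner reading stays below that. The array medians over all probes lay between 5.56 and 5.59, and the SDs were 1.85 and 1.89 with Rg5 against 1.80 on both arrays with vehicle. The number of arrays limits the precision of every value.

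Probes were named through a platform table that pairs probe identifiers with gene symbols. A single symbol was given for 11707 probes and several symbols for 0, and the remaining 6968 are unnamed here. All 11707 Entrez identifiers matched a table of current human gene names made for assembly GRCh38.p14, which changed 0 symbols. Of genes with more than 1 probe, of which there were 15, the probe with the highest mean over the 4 arrays was kept, which left 11692 genes.

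The arms were compared on the log2 values as deposited with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with 1 prior for all genes, a two-sided test and Benjamini-Hochberg adjustment over the 11692 genes at a threshold of 0.05. With 2 arrays an arm the fit had 2 residual degrees of freedom for each gene, and the prior added 3.72. A second count required a change of at least 2-fold as well. An exact permutation test of a single gene with 2 arrays against 2 cannot give a two-sided p below 0.333, so no such test was used. No count of other splits was made, because groups of 2 allow too few. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

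The groups, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold whose Rg5 arrays both lay on the same side of both vehicle arrays, leaving out uncharacterised loci and small RNA genes. Places left over in a direction were filled from the smallest unadjusted p. It also took up to 4 members past the threshold from each gene list called by the set test and up to 2 from every other list. A further 12 genes were to be reported whatever their values, and 6 of them (CXCL8, PTGS2, EGFR, HMOX1, ANXA1 and FPR2) were measured, while the other 6 are not analysed here. Any other gene named in the text was chosen after its values were seen.

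Gene lists, 33 in number, were also fixed in advance from general knowledge of the pathways and cell types. They cover airway mucins, goblet and secretory cell genes, inflammatory cytokines and chemokines, NF-kB feedback targets, AP-1 and immediate early genes, and EGFR ligands with ERK feedback genes. Others hold matrix proteases with the plasminogen system, lipid mediator and resolution genes, NRF2 targets, cholesterol synthesis with SREBP2 targets, fatty acid synthesis with SREBP1 targets, and LXR targets with cholesterol efflux genes. Stress and growth were covered by ER chaperones with the unfolded protein response, the ATF4 amino acid response, cytosolic heat shock, hypoxia and glycolysis, p53 targets, mitotic genes, and DNA replication genes. The remaining lists hold interferon-stimulated genes, epithelial junction genes, mesenchymal genes, squamous and cornified envelope genes, AHR and xenobiotic response genes, glucocorticoid receptor targets, TGF-beta and YAP targets, and lysosome and autophagy genes. Markers of leukocytes, of fibroblasts and endothelium, and of ciliated cells, with ribosomal protein, oxidative phosphorylation and housekeeping genes, completed them. Each list with a measured member was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists tested, and its members were counted past the threshold over all genes and adjusted over the list alone. The adjustment over a list alone was made in each list separately, with no correction across the lists. A member passing only that way has weaker evidence than a gene passing over all genes.

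The alternatives were quantile normalization, centring each array on its median, a prior that follows the mean level, a robust prior, leaving out the dimmest 25% of genes, the replicate number as a block, leaving out each array in turn, the mean of all probes of a gene, a stricter fold limit, camera with an estimated correlation, and fry. Camera with an estimated correlation refers its statistic to the 2 residual degrees of freedom of the fit. With the preset correlation it takes nearly as many degrees of freedom as there are genes. Fitting all 18675 probes at once and cyclic loess were added after seeing the data. The robust prior was not run for the gene lists, because camera has no such setting. Neither cyclic loess nor the fit of all probes was run for the fixed gene lists. The steps were tested on simulated data with 200 of 11692 genes changed in 20 draws of this comparison. They recovered 78.7% of changes of 1 and 98.4% of changes of 2 on the log2 scale, with 4.81% false among the calls. A simulated list of 20 genes shifted by 0.5 had an unadjusted camera p below 0.05 in 20 of 20 draws, and an unshifted one in 0. The simulated noise was independent between genes, with variances drawn from the fitted prior whatever the signal level. These rates therefore do not cover correlated genes, a spread that varies with level, or the adjustment over lists.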

Results

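Gene expression was measured in NCI-H292 cells, a human airway mucoepidermoid carcinoma line that serves as a model of mucus-producing epithelium. All 4 arrays came from cells exposed to PMA, a protein kinase C activator used to provoke inflammatory and mucin gene expression, at 10 ng/ml with 24 h given as the time. In 1 arm of 2 arrays the cells also received Rg5, a triterpene saponin of processed ginseng, and in the other arm of 2 arrays they received vehicle. The Rg5 dose was not stated, and the wording of the labels left open which of Rg5 and PMA came first. Because no arm without PMA was analysed here, each change is relative to PMA-treated cells given vehicle. Nothing stated that replicates were separate cultures. The p-values of single genes and of fry therefore measure only the spread between these arrays, which may be technical. Camera at the preset correlation compares the members of a list with the other genes and takes genes as its units. Its small p-values do not measure how a change would vary between arrays or cultures. Across genes, which are not independent replicates, arrays of the same arm correlated with r of 0.993 (Rg5) and 0.991 (vehicle), and arrays of different arms with r between 0.984 and 0.988. The SD of the difference between arrays was 0.22 and 0.23 log2 units within the arms and between 0.28 and 0.33 across them.

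The comparison asked how Rg5 alters the transcriptome of PMA-treated airway mucous cells. With Rg5, 6 of 17 measured cholesterol synthesis genes and SREBP2 targets rose, as did the AP-1 subunits JUN and JUND and the Krüppel-like factors KLF2, KLF6 and KLF7. The largest rise was that of RHOB, a small GTPase that acts on actin and endosomal traffic. RHOB stood at 9.88 ± 0.015 (SD, n = 2) with Rg5 against 6.30 ± 0.15 (SD, n = 2) with vehicle, a rise of 3.58 on the log2 scale. INSIG1, the endoplasmic reticulum protein that restrains SREBP processing and HMG-CoA reductase, rose 8.98-fold, and KLF2, a zinc finger transcription factor, rose 5.93-fold. In the opposite direction, DUSP6, a phosphatase that inactivates ERK, fell by 1.16 on the log2 scale, and AIM2, a cytosolic sensor of double-stranded DNA, fell by 1.12. Every called gene had both Rg5 arrays on the same side of both vehicle arrays. In all, 24 genes were higher and 3 lower among 11692 genes tested with limma, and 25 of these 27 genes changed at least 2-fold, 23 of them upward.

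**Figure D1:**
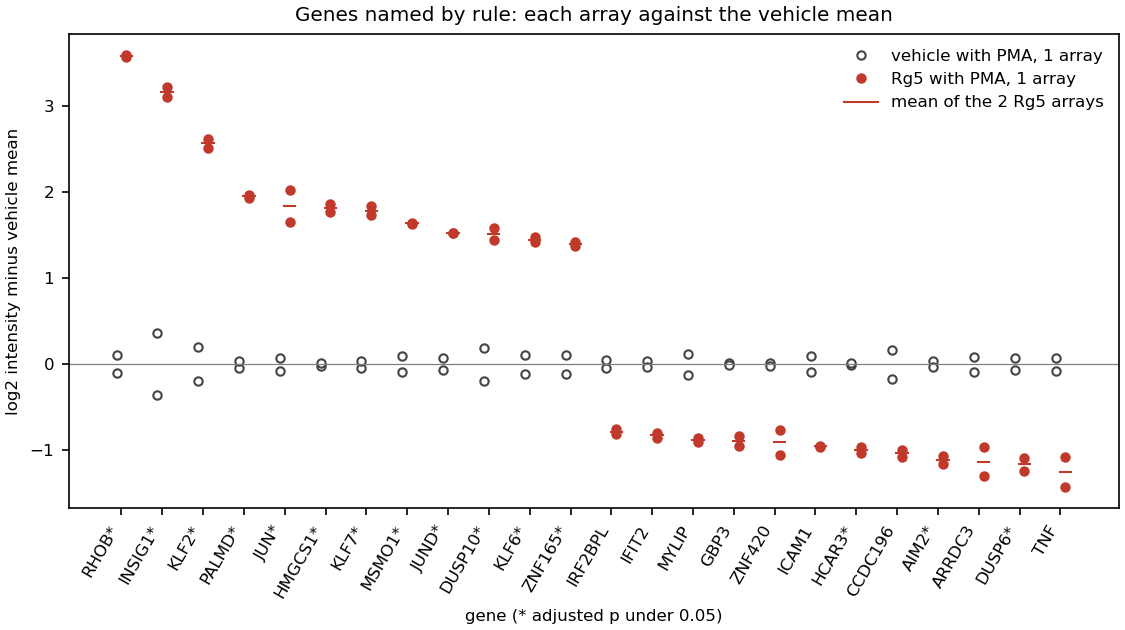
Log2 intensity of each array minus the vehicle mean (vertical axis, log2 units) for the 24 genes taken by size or rank (horizontal axis); open points are the 2 vehicle arrays, filled points the 2 Rg5 arrays and bars the Rg5 mean, with an asterisk where the limma adjusted p passed 0.05. The RHOB arrays lie 3.58 log2 units above the vehicle mean on average, and both Rg5 arrays lie on the same side of both vehicle arrays for every gene shown. The naming rule required this of the genes past the threshold, and taking the others by smallest p favours it.

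The 12 largest rises ran from 3.58 for RHOB (SE 0.12, limma adjusted p = 0.0016) to 1.40 for ZNF165, a zinc finger protein (SE 0.12, adjusted p = 0.0226). INSIG1 rose by 3.17 (SE 0.24, adjusted p = 0.0208) and KLF2 by 2.57 (SE 0.15, adjusted p = 0.0106). PALMD, a member of the paralemmin family, rose by 1.95 (SE 0.10) and KLF7, another Krüppel-like factor, by 1.79 (SE 0.10), both at an adjusted p of 0.0106 from limma. DUSP10, a phosphatase of stress-activated MAP kinases, rose by 1.51 (SE 0.15, limma adjusted p = 0.0432). JUN, HMGCS1, MSMO1, JUND and KLF6 made up the rest of the 12 and are described with their groups. The called genes outside the 12 were IDI1, SQLE, STARD4 and LPIN1, also described with their groups, and 8 more that were named after their values were seen. Among these, FGFBP1, a secreted carrier of fibroblast growth factors, rose by 1.35, SHOC1 and RIMKLB by 1.24 each, MTHFD2L, a mitochondrial folate enzyme, by 1.20, and the deubiquitinase YOD1 by 1.18. FHDC1 rose by 1.07, RASSF8 by 1.01 and the phospholipase PNPLA8 by 0.96.

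Of the cholesterol synthesis and SREBP2 targets, 17 of 26 were measured, and all 17 had a positive log2 fold change. Among them 6 rose over all genes tested and 13 when adjusted over the list alone, none fell, and the median log2 fold change was 0.75. Behind INSIG1 came HMGCS1, the cytosolic HMG-CoA synthase, with a rise of 1.82 (SE 0.10, limma adjusted p = 0.0106), and MSMO1, a sterol demethylation enzyme, with 1.64 (SE 0.11, adjusted p = 0.0168). IDI1, the isopentenyl diphosphate isomerase, rose by 1.35 (SE 0.11, limma adjusted p = 0.0208). SQLE, the squalene epoxidase, rose by 1.30 and STARD4, a sterol carrier, by 1.11. Over the list alone 7 more passed, with HSD17B7 at 1.10, DHCR7 at 0.81, FDPS at 0.75 and ACAT2 at 0.74, and with MVD at 0.46 (0.29 to 0.63 without 1 array), NSDHL at 0.41 (0.25 to 0.57) and MVK at 0.27. The camera adjusted p of the list was 1.57e-15. With an estimated correlation of 0.12, and thus on 2 degrees of freedom, the camera adjusted p was 0.748 and the unadjusted camera p was 0.0339. Fatty acid synthesis and SREBP1 targets had 1 riser among 17 measured, LPIN1, a phosphatidate phosphatase, at 1.10 (SE 0.10, limma adjusted p = 0.0328), and 4 when adjusted over the list alone. The list median was 0.11 and ran from 0.083 to 0.19 without 1 array (camera adjusted p = 0.0162, and adjusted p = 0.748 with an estimated correlation), SCD, the stearoyl-CoA desaturase, stood at 0.71, and ACSS2, a cytosolic acetyl-CoA synthetase, at 0.56. That camera call was lost after quantile normalization (adjusted p = 0.085), without Rg5 replicate 1 (adjusted p = 0.0672) and without vehicle replicate 2 (adjusted p = 0.0951). LXR targets and cholesterol efflux genes had 6 measured members, none past the threshold, with a median of -0.013 and a camera adjusted p of 0.678, and MYLIP, a ubiquitin ligase for the LDL receptor, was lower over the list alone at -0.88.

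Of 17 measured AP-1 and immediate early genes, 4 rose, none fell and 13 did not pass, and adjusted over the list alone 8 were higher and 2 lower. JUN rose by 1.84 (SE 0.15, limma adjusted p = 0.0226) and JUND by 1.52 (SE 0.11, adjusted p = 0.0170), and both encode subunits of AP-1. The other risers were KLF2 and KLF6, Krüppel-like factors that are not AP-1 subunits, with KLF6 up by 1.45 (SE 0.12, limma adjusted p = 0.0226). FOSB at 1.30, ATF3 at 0.89, KLF10 at 0.48 and KLF4 at 0.35 passed over the list alone only, as did the lower members JUNB at -0.68 and EGR1 at -0.77, the latter between -1.15 and -0.38 in fits without 1 array. The list median was 0.26, with a camera adjusted p of 0.0043, and 0.748 as the adjusted p with an estimated correlation. The estimated correlations were -0.041 for this list and -0.040 for the fatty acid list, both below the preset 0.01. A higher correlation was thus not what took away these 2 calls, which were lost on the 2 degrees of freedom of that setting. The cholesterol list met the same drop in degrees of freedom, besides its higher correlation of 0.12. Few lists could pass on 2 degrees of freedom, so these losses count little against the lists.

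**Figure D2:**
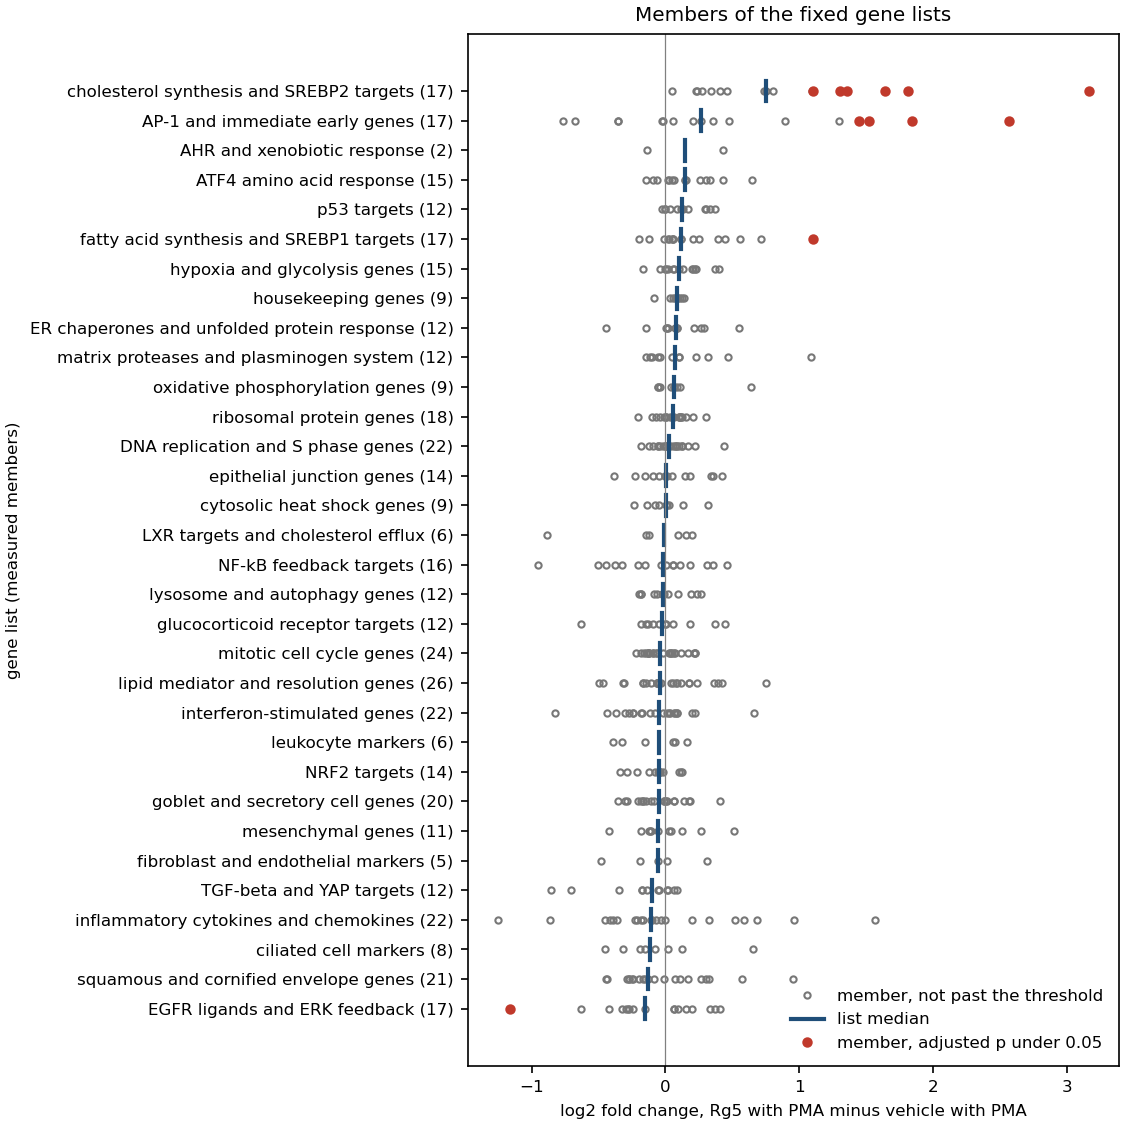
Log2 fold change, Rg5 with PMA minus vehicle with PMA (horizontal axis), of each measured member of the gene lists (vertical axis, number of measured members in brackets); filled points passed the limma threshold over all genes, open points did not, and bars mark list medians. The 17 members of the cholesterol synthesis list lie above 0 with a median of 0.75, and every other list shown has members on both sides of 0.

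The falls that passed were DUSP6 at -1.16 (SE 0.11, limma adjusted p = 0.0397), AIM2 at -1.12 (SE 0.10, adjusted p = 0.0328) and HCAR3, a G protein-coupled receptor of hydroxycarboxylic acids, at -0.996 (SE 0.099, adjusted p = 0.0397). The next 9 by smallest p did not pass. They included the interferon-inducible genes GBP3 at -0.89 (limma adjusted p = 0.057) and IFIT2 at -0.83, and the cytokine TNF at -1.25 (limma adjusted p = 0.0583). The adhesion molecule ICAM1 stood at -0.95 and MYLIP at -0.88. ARRDC3, of the arrestin family, stood at -1.14, CCDC196 at -1.04, ZNF420 at -0.91 and IRF2BPL at -0.78, and the highest adjusted p of these 9 was 0.079. DUSP6 was the only member of the 17 measured EGFR ligands and ERK feedback genes past the threshold. Adjusted over the list alone, ERRFI1, a feedback inhibitor of EGFR, at -0.63 and the EGFR ligand HBEGF at -0.42 were lower as well, and the phosphatase DUSP4 at 0.41 was higher. The camera adjusted p of that list was 0.528 with a median of -0.15, while fry, which asks only whether a list's own members lean one way, gave an adjusted p of 0.0251. Without vehicle replicate 1 the median was -0.0046. EGFR itself stood at -0.15 (limma adjusted p = 0.532).

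None of the 22 measured inflammatory cytokines and chemokines passed over all genes, and adjusted over the list alone 6 were higher and 5 lower. The higher members were IL24 at 1.56, IL11 at 0.96, IL33 at 0.68, TSLP at 0.58, CXCL3 at 0.52 (0.34 to 0.70 without 1 array) and CXCL5 at 0.33, and the lower ones were TNF at -1.25, CCL2 at -0.86, CXCL11 at -0.41, CSF1 at -0.39 and LIF at -0.36. The median of -0.11 and the camera direction were downward and the mean of 4e-04 was not (camera adjusted p = 0.631). The neutrophil chemokine CXCL8 stood at -0.21 (limma adjusted p = 0.546), and at 0.0044 without vehicle replicate 2. The 16 measured NF-kB feedback targets had a median of -0.016 (camera adjusted p = 0.631), with ICAM1 lower and REL, an NF-kB subunit, higher at 0.46 over the list alone. Interferon-stimulated genes, 22 measured, had a median of -0.047 (camera adjusted p = 0.416, and -0.086 to -0.041 without 1 array), with IFIT2 lower and the exonuclease ISG20 higher at 0.66 over the list alone. Of the 26 measured lipid mediator and resolution genes none passed, and ANXA1, the glucocorticoid-regulated pro-resolving protein annexin A1, was higher over the list alone. ANXA1 stood at 0.75 (SE 0.10, limma adjusted p = 0.0772), PTGS2, the inducible cyclooxygenase, at 0.43 (adjusted p = 0.181) and FPR2, a receptor of annexin A1, at -0.050 (adjusted p = 0.936). The sign of FPR2 turned after quantile normalization (0.051) and without Rg5 replicate 1 (0.30) or vehicle replicate 1 (0.084). The median of this list was -0.041 while its mean of 0.015 and camera direction were upward (camera adjusted p = 0.919). HMOX1, the inducible heme oxygenase, stood at -0.29 (limma adjusted p = 0.363) within NRF2 targets, whose 14 measured members had a median of -0.050 (camera adjusted p = 0.528, and -0.072 to -0.025 without 1 array).

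No airway mucin of the list of 14 was analysed here, and no member of the other lists of cell type and tissue structure passed over all genes. Goblet and secretory cell genes had 20 measured members, a median of -0.050 (0.039 without vehicle replicate 1) and a camera adjusted p of 0.631. Squamous and cornified envelope genes (21 measured) had a median of -0.13 (camera adjusted p = 0.631, and medians between -0.085 and -0.039 without 1 array), with the desmosomal cadherin DSC2 at 0.96 passing over the list alone. TGF-beta and YAP targets (12 measured) had a median of -0.099 (-0.15 to -0.073 without 1 array) with a camera adjusted p of 0.114, and fry gave an adjusted p of 0.00651. The growth factor-like matrix protein CCN2 at -0.85 and the junction protein AMOTL2 at -0.70 were lower in that list over the list alone. Matrix proteases and the plasminogen system (12 measured) had a median of 0.075 (camera adjusted p = 0.528), with MMP10, a stromelysin, at 1.09 passing over the list alone. Medians of the epithelial junction list (14 measured, 0.0047, camera adjusted p = 0.631) and of the mesenchymal list (11 measured, -0.054, camera adjusted p = 0.919) were small, and the direction of both set tests turned after quantile normalization. Leukocyte markers (6 measured) had a median of -0.049 (camera adjusted p = 0.621), and -0.12 to -0.039 without 1 array. Fibroblast and endothelial markers had -0.056 (5 measured, camera adjusted p = 0.82) and ciliated cell markers -0.12 (8 measured, camera adjusted p = 0.678), with TEKT1 at 0.65 passing over the ciliated list alone, and both of these set tests turned direction after quantile normalization. Without 1 array the ciliated median lay between -0.17 and -0.010.

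Lists of stress and growth genes had no member past the threshold over all genes. The ATF4 amino acid response had a median of 0.14 (15 measured, camera adjusted p = 0.121), p53 targets 0.13 (12 measured, adjusted p = 0.114) and hypoxia and glycolysis genes 0.10 (15 measured, adjusted p = 0.167). In fits without 1 array these medians fell as low as 0.046, 0.060 and 0.025. ER chaperones and the unfolded protein response had a median of 0.077 (12 measured, camera adjusted p = 0.48, and 0.049 to 0.082 without 1 array), with the sensor kinase EIF2AK3 at 0.55 higher and the sensor ERN1 at -0.45 lower over the list alone. Cytosolic heat shock genes (9 measured) had a median of 0.0034 and a mean of -0.00085, and lysosome and autophagy genes (12 measured) a median of -0.019 and a mean of 0.0045, with a downward camera direction and an adjusted p of 0.919 in both. The 2 measured AHR and xenobiotic response genes had a median of 0.15 (camera adjusted p = 0.631), with TIPARP, a target of AHR, at 0.43 passing over the list alone. Glucocorticoid receptor targets (12 measured) had a median of -0.028 (camera adjusted p = 0.919), a direction that turned after quantile normalization, and ERRFI1 was lower over the list alone. Mitotic genes had a median of -0.039 (24 measured, camera adjusted p = 0.746), and oxidative phosphorylation genes 0.063 (9 measured, camera adjusted p = 0.621) with UQCRB, a subunit of respiratory complex III, at 0.64 passing over the list alone. DNA replication genes at 0.030 (22 measured, camera adjusted p = 0.631), ribosomal protein genes at 0.055 (18 measured, adjusted p = 0.627) and housekeeping genes at 0.088 (9 measured, adjusted p = 0.528) had upward set tests that turned after quantile normalization. Without 1 array the median was as low as 0.028 for housekeeping and 0.032 for oxidative phosphorylation genes. Beside these small medians, that of all genes was not level with signal, since the median log2 fold change went from -0.084 in the dimmest 25% of genes to 0.070 in the brightest 25%.

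**Figure D3:**
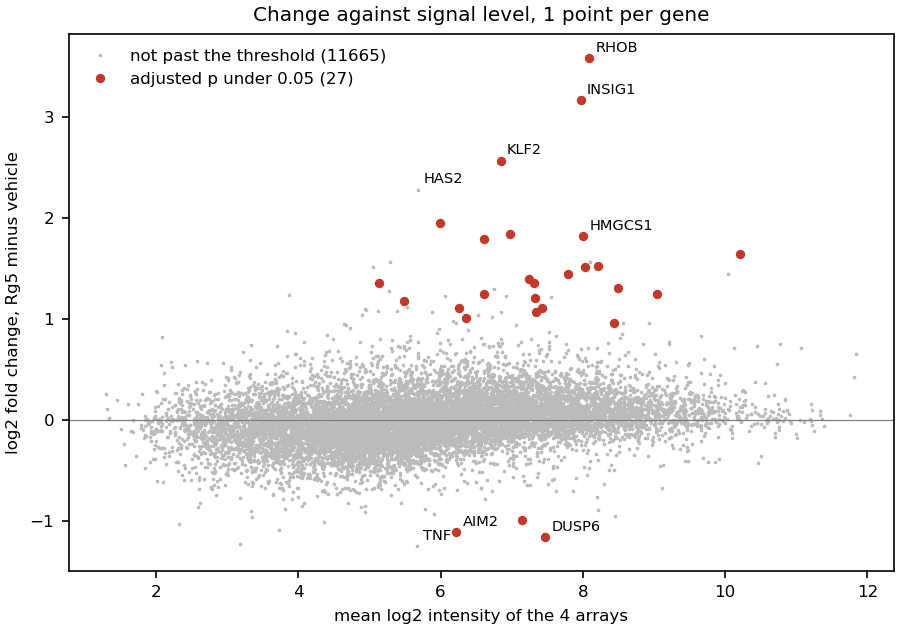
Log2 fold change, Rg5 with PMA minus vehicle with PMA (vertical axis), against the mean log2 intensity of the 4 arrays (horizontal axis) for the 11692 genes; filled points are the 27 genes past the limma threshold. The 24 higher genes include 16 in the brightest 25% of genes and 0 in the dimmest 25%, and HAS2 and TNF lie far from 0 without passing.

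By set test, 3 of the 32 lists were higher and 0 lower, 7 lists had an unadjusted camera p below 0.05, fry called 3 higher and 2 lower, and no list was called by camera with an estimated correlation. At an unadjusted limma p below 0.05 there were 1117 genes higher and 965 lower, against 584.6 that chance would give in both directions together. Both Rg5 arrays lay above both vehicle arrays for 3022 genes and below for 2745, together 49.3% of genes against the 33.3% that chance gives. Fits of 3 arrays, which have 1 residual degree of freedom, called 0 genes without Rg5 replicate 1 or Rg5 replicate 2, 3 without vehicle replicate 1 and 1 without vehicle replicate 2, while the log2 fold changes of RHOB stayed between 3.47 and 3.69, of HMGCS1 between 1.77 and 1.86 and of DUSP6 between -1.24 and -1.09. A prior that follows the mean level called 457 higher and 142 lower, leaving out the dimmest 25% of genes 125 higher and 32 lower, and quantile normalization 15 higher and 2 lower, with DUSP6, DUSP10, ZNF165, LPIN1 and STARD4 among the calls lost.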

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

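The fit behind this result was chosen after seeing the data. The comparison in the report used named genes, and 6968 further probes are unnamed here. When all 18675 probes were fitted together with limma, 1 unnamed probe passed the threshold, and it was singled out because it lies outside the main measurement and was higher with Rg5 than with vehicle. This was probe 16924602, with a log2 fold change of 1.68 (SE 0.12, limma adjusted p = 0.0381). In the same fit 11 named genes were higher and 0 lower, and 1176 of the unnamed probes had an unadjusted p below 0.05. What the probe measures was not tested.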

How the results depend on the processing

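Fitting all probes at once and cyclic loess were added after seeing the data, and the other alternatives were planned. Of 85 genes followed, which include all 27 called ones, only FPR2 and CXCL8 changed direction under any alternative, and neither was called. Rises, falls and changes of at least 2-fold numbered 24, 3 and 25 in the report, and 15, 2 and 17 with quantile normalization or cyclic loess. The counts were 457, 142 and 53 with the prior that follows the mean level, 125, 32 and 43 with the dimmest 25% of genes left out, and 11, 0 and 11 with all probes in one fit. The cause of these moves, the filter's included, was not tested. In the fit of all probes 910 named genes were lower at an unadjusted limma p below 0.05. Leaving out 1 array gave between 0 and 3 rises, 0 falls and between 0 and 3 changes of at least 2-fold, and the lone array left in an arm was assumed to vary like those of the other arm, so these fits have fewer samples. At an unadjusted limma p below 0.05 they had 855 and 899 genes higher and lower without Rg5 replicate 1, 534 and 558 without Rg5 replicate 2, 732 and 772 without vehicle replicate 1, and 856 and 749 without vehicle replicate 2. A fold limit of 1.5 on the log2 scale left 10 genes. Median centring gave 30 rises, 3 falls and 30 changes, the robust prior 20, 3 and 22, and the mean of all probes no other count. With the replicate number as a block, 1 gene was higher, 0 were lower and 1 changed at least 2-fold (1029 and 996 at an unadjusted limma p below 0.05), and the block also called 3 lists higher and 0 lower. Arrays of the same number deviated from their arm means with a correlation of 0.011 across genes, so the numbers were not taken to pair the arrays. The called genes that lost their call numbered 10 under quantile normalization and 10 under cyclic loess (DUSP10, ZNF165, DUSP6, LPIN1, STARD4, MTHFD2L, YOD1, FHDC1, RASSF8 and PNPLA8 in both), 4 under the robust prior and 16 with all probes in one fit. Without vehicle replicate 1 the 3 calls were RHOB, INSIG1 and KLF2, and without vehicle replicate 2 the 1 call was RHOB. Under the prior that follows the mean level 44 more of the genes followed were called, among them ANXA1 (limma adjusted p = 7.97e-05) and TNF (adjusted p = 0.00141). Over all fits the limma adjusted p reached 0.458 for ANXA1 and 0.307 for TNF. ANXA1 and TNF also passed with the dimmest genes left out (limma adjusted p = 0.0256 and 0.0174), and IL24 after median centring (adjusted p = 0.0407, between 9.49e-05 and 0.458 over all fits).

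Lists called higher and lower numbered 3 and 0 in the report, 2 and 0 with quantile normalization, 3 and 1 with the dimmest genes left out or the prior that follows the mean level, 0 and 0 with camera's estimated correlation, and 3 and 2 with fry. Without 1 array between 2 and 3 lists were higher and 0 lower. The list that became lower was TGF-beta and YAP targets, with a median of -0.18 and a camera adjusted p of 0.0164 without the dimmest genes, and 0.0371 with the level-following prior. The set tests of uncalled lists turned direction in some fits, uncalled before and after, and the cause was not tested. After quantile normalization the medians of those that turned were -0.064 for DNA replication, -0.038 for epithelial junctions, -0.019 for mesenchymal genes, 0.020 for glucocorticoid targets, 0.036 for fibroblast and endothelial markers, -0.055 for ciliated cells, -0.017 for ribosomal proteins and 0.0040 for housekeeping genes. Without the dimmest genes the mesenchymal median was 0.026 and the fibroblast and endothelial one 0.061. Over the fits without 1 array, medians ran from -0.067 to -0.0028 for mitotic genes, from -0.038 to 0.019 for heat shock, from -0.070 to 0.096 for lipid mediators, from -0.073 to 0.047 for mesenchymal genes and from -0.080 to 0.086 for glucocorticoid targets. They ran from -0.042 to 0.011 for lysosome genes, from -0.20 to 0.12 for fibroblast and endothelial markers, from -0.066 to 0.085 for matrix proteases, from -0.18 to -0.011 for cytokines, from -0.0040 to 0.076 for DNA replication and from 0.014 to 0.11 for ribosomal proteins. Medians of 3 other lists changed sign, from -0.076 to 0.039 for goblet genes, from -0.027 to 0.022 for LXR targets and from -0.015 to 0.059 for epithelial junctions. Those of the ATF4 response ran from 0.046 to 0.21, of p53 targets from 0.060 to 0.21, of hypoxia genes from 0.025 to 0.13, of the EGFR list from -0.15 to -0.0046 and of NF-kB targets from -0.067 to -0.017. HMOX1 ran from -0.43 to -0.15, EGFR from -0.24 to -0.062 and TSLP from 0.35 to 0.82. FPR2 stood at 0.051 after quantile normalization, at 0.043 after cyclic loess and between -0.40 and 0.30 without 1 array, and CXCL8 between -0.43 and 0.0044. Signal over background was not given, and the median residual SD fell from 0.16 in the dimmest 25% of genes to 0.072 in the brightest 25%, so small changes of dim genes were the hardest to call.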

Other observations

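The family scan below and the test of rises against falls by level were chosen after the values were seen, and the other tests had their predictions written first. Krüppel-like factors are zinc finger transcription factors that bind GC-rich promoter elements. Among 15 measured members 9 had a positive log2 fold change and 3 passed the threshold, KLF2, KLF7 and KLF6. KLF11 at 0.73 (0.49 to 0.97 without 1 array) and KLF3 at 0.60 came next without passing, and KLF14 at -0.40 was the lowest. In a scan of 155 families of at least 10 genes sharing a symbol stem, camera called 6, of which 2 were upward. The KLF family had a median of 0.35 (camera adjusted p = 0.0137, and 0.00808 after quantile normalization), but a median of 0.11 without its 3 called members, and the estimated correlation gave an adjusted p of 0.921. With that correlation 0 of the 6 families were called, each at an adjusted p of 0.921. On the 2 degrees of freedom of that setting hardly any family could pass among 155, so this counts little against them. The USP deubiquitinases had a median of 0.12 (camera adjusted p = 0.0137), and the 4 lower families were HOXB, NKX, KRTAP and KLK, with medians of -0.28, -0.22, -0.098 and -0.22. HOXB and KRTAP had median levels within the dimmest 25% of genes, where the median of all genes was -0.084, so KRTAP lay near that value, and NKX and KLK within the next 25%, where it was -0.061. KLF and USP lay in the 25% above these, with 0.032 for all genes. After quantile normalization all 6 kept their direction and 1 was called, the KLF family.

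HAS2, a hyaluronan synthase, had the largest change among genes that did not pass, 2.28 (SE 0.36, limma adjusted p = 0.0929), with SDs of 0.50 and 0.65 in the arms. GEM, a small GTPase of the RGK family, stood at 1.56 and IL24, a cytokine of the interleukin-10 family, at 1.56 (SE 0.17, limma adjusted p = 0.0509).

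The higher cholesterol synthesis list was set against a trend of the change with signal level and against a single array carrying it. Minus genes of the same mean level, the list median was 0.71, above all 10000 level-matched random lists, whose largest median was 0.26, which argues against the level trend as its cause. The smallest list median over the 4 pairs of an Rg5 and a vehicle array was 0.73 and the largest 0.79, while the medians between arrays of 1 arm were -0.044 and 0.15, which argues against a single array. An effect of Rg5 stays a hypothesis, found and tested on the same arrays. A difference in culture or handling between the arms was not tested and cannot be told apart from Rg5 with these arrays.

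Rises outnumbered falls among the called genes, 88.9% of 27 (exact 95% binomial interval 70.8% to 97.7%, which treats genes as independent). The balance was closer over more genes, with 1117 higher and 965 lower at an unadjusted limma p below 0.05, and 982 and 903 after quantile normalization. The share was 76.3% with the prior that follows the mean level and 79.6% with the dimmest 25% of genes left out. Under quantile normalization and under cyclic loess it was 88.2%, but the bound set for this test was a wrong one and the share decides nothing about scaling or a level trend, because all 17 calls in each were among the 27 and every one of the 27 had changed by at least 0.955. The median change of the brightest 25% of genes lay 0.15 above that of the dimmest 25% (-0.017 after cyclic loess). The median of all genes lay between -0.0095 and 0.015 under the scalings tried. Shifts of these sizes are too small to turn the direction of any of the 27 called genes. Whatever the p, 45 genes were at least 2-fold higher and 8 lower. Small shifts could still decide which genes pass, so whether scaling, level or Rg5 set the share stays open.

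For the higher RHOB and KLF2, a hypothesis of lower MRTF-SRF signalling was tested with a list of 30 cytoskeletal targets of MRTF and SRF, of which 17 were measured, and predicted a median below -0.1. The median was 0.12, and 15 of the 17 were positive (camera p = 0.00573 upward, and p = 0.113 with an estimated correlation), the opposite of the prediction. After cyclic loess the median was 0.082, so the list gives no sign of lower MRTF-SRF output in these arrays. Other routes to higher RHOB and KLF2 were not tested.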
